A study of Homo sapiens with 40 samples.

How the data were processed

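Gene expression was measured on Affymetrix HG-U133 Plus 2.0 arrays in 40 skin biopsies from 18 patients with atopic dermatitis. Per the labels' protocols, total RNA was column-extracted with DNase treatment and biotin-labelled. The labels give each biopsy's tissue (lesional or non-lesional), its visit (before or after treatment), the patient and the arm. The arms were dupilumab 150 mg (7 patients), dupilumab 300 mg (7 patients) and placebo (4 patients). The interval between the visits is not given in the sources used here. One biopsy carries a title (non-lesional) and a tissue tag (lesional) that disagree. It was assigned by the tag, which gives the lesional and non-lesional totals of the series' design text. It thus counts as lesional before dupilumab 150 mg and is the baseline of that patient's lesional pair. The paired changes at 150 mg and at both doses include it.

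The deposited values are on a log2 scale and, per the submitters' processing notes, were made by the authors with GCRMA, which corrects probes for background by their GC content, normalizes quantiles between arrays and summarizes probe sets. The version of GCRMA is not given in the sources used here. The values ran from -1.92 to 17.1 over 38865 probe sets, with array medians between 6.98 and 7.36. On 16 arrays the lowest value shared by many probe sets was the GCRMA floor of 2.13. On the others that floor was displaced by an amount that differed between probe sets, which divides the 40 arrays into 3 sets of 16, 16 and 8 arrays, called array sets A, B and C here. The mean of every probe set over set B equalled that over set A to within 1e-08. Set C held non-lesional biopsies only. The labels record neither these sets nor the step that shifted them, so any adjustment between them was taken as deposited. The implied shift of set B had a median size of 0.30 log2 over the tested genes and exceeded a size of 0.5 log2 for 29.2% of them. Values of lesional against non-lesional skin therefore depend on that unrecorded step, whereas the 9 dupilumab-treated patients with lesional biopsies from both visits each had both of them in one set.

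Probe sets were named from the platform annotation supplied with the data. Of 38865 probe sets, 30454 had one gene symbol, 1406 had several and were not used, and 7005 were not listed and are unnamed here. Before any analysis, 49 probe sets of sex-linked genes were removed. Probe sets were kept when they exceeded 4 on the log2 scale in at least 5 of the 40 arrays, whatever their group, and each gene was represented by its kept probe set with the highest mean over all arrays, which left 13345 of 15480 genes.

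The values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with one mean for each of the 10 groups of tissue, visit and arm, so that all groups shared one estimate of the spread with 30 residual degrees of freedom. The patient was a random block with a correlation of 0.0746 estimated by duplicateCorrelation. The pairing comes from the patient labels. Deviations from the group means correlated with a median r of 0.0771 over the 38 array pairs of one patient and -0.0236 over 668 pairs of different patients, across genes, and 16 of the 38 exceeded 0.1. There were 9 comparisons: lesional against non-lesional skin before treatment, lesional skin after against before treatment at each dose, at both doses together and under placebo, the difference between doses, the difference between dupilumab and placebo, non-lesional skin after against before dupilumab, and lesional against non-lesional skin after dupilumab. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with calls at an adjusted p under 0.05.

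The comparisons, the rule for named genes, the alternatives listed last and 23 gene lists of skin pathways and cell types were fixed before the data were examined. The lists are type 2 cytokines and receptors, type 2 chemokines with IL-4/IL-13 response genes, IL-17/IL-22 axis and antimicrobial genes, interferon and Th1 genes, wound-type keratins, proliferation, epidermal differentiation and junctions, barrier lipids, sebaceous gland, T cells, dendritic cells, macrophages, mast cells and basophils, eosinophils and neutrophils, B and plasma cells, melanocytes, fibroblasts, endothelium, eccrine gland, hair follicle, adipocytes, muscle and housekeeping. Of their 285 genes, 225 were tested, and 22 lists had at least 2 tested members (of the wound-type keratins only KRT16 was measured). List shifts were tested with limma's cameraPR on the moderated statistics, with the correlation between genes preset at 0.01 and, as an alternative, estimated from the residuals, each adjusted over the 22 lists of a comparison. The mean log2 value of a list's members was also compared within patients by an exact two-sided sign-flip permutation test.

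A lesional signature score was the mean of 200 genes minus the mean of 200 others, those with the highest and lowest moderated statistic for lesional against non-lesional skin before treatment. The genes were picked from the biopsies of the other dupilumab arm, so that no patient's own biopsies were used to pick the genes scored in them. The arms are still not fully independent, since array sets that were adjusted to each other held biopsies of both arms. Placebo arrays were scored with genes from both dupilumab arms. Its paired changes were tested by exact two-sided sign-flip and its differences between groups by exact two-sided permutation tests. The test over both doses together was added later. The genes named were fixed by rule: a panel of 16 genes (15 tested, since IL13 did not pass the filter); the 5 largest rises and 5 largest falls among called genes with the same sign in at least 2 of 3 paired patients; up to 3 called members of each list; and, where no gene was called, the 5 with the smallest p. Genes whose level follows common germline deletions or haplotypes were left out of the naming. Genes named because they passed adjusted over their list alone were chosen after their values were seen.

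The pipeline was tested on simulated data with 13345 genes. The simulation held no array sets and no GCRMA floor, so its recovery is not the power of the real comparisons. Of 100 genes changed by 1 log2, 56 were recovered for lesional against non-lesional skin before treatment, 43 at 150 mg, 29 at 300 mg, 62 at both doses and 13 under placebo. Of 100 changed by 2 log2, the numbers were 97, 88, 70, 94 and 56. A simulated list shift of -0.5 log2 in independent genes was called in 10 of 10 draws, with 2 false calls among 210 lists tested; real list members are correlated, which this does not cover.

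The alternatives covered the patient block, the filter on dim probe sets, the probe set rule, the normalization, array weights, the samples in the fit, the biopsy with conflicting labels, the threshold, the variance prior, the signature size and source, and leaving out each of the 18 patients with all of that patient's biopsies. All of them were run for single genes or the signature score. List shifts were not run with the fixed block, the stricter filter, the mean of probe sets, centring of arrays or array weights. Nor were they run without the biopsy with conflicting labels, with only the groups compared, or under the other threshold or variance prior. With only the placebo groups in the fit the block correlation could not be estimated, so those arrays were taken as independent. Refits used 3000 genes to estimate the block correlation. Alternatives with the array set, as a fixed term, within a set or without set C, were added after the data were examined. The number of arrays per group, from 2 to 7, limits the precision.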

Results

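The 40 biopsies were of lesional and non-lesional skin, taken before and after treatment with dupilumab, an antibody that binds the interleukin-4 receptor alpha chain and blocks the signals of IL-4 and IL-13, or with placebo. Before treatment there were 7 lesional biopsies in the 150 mg arm, 6 in the 300 mg arm and 3 in the placebo arm, with 3 and 4 non-lesional biopsies in the dupilumab arms. After treatment there were 6, 4 and 2 lesional and 2 and 3 non-lesional biopsies. No non-lesional biopsy came from the placebo arm. Each value is a log2 GCRMA intensity of a probe set, so a difference of 1 is a doubling, and errors of differences are standard errors from limma unless given as SD. The arrays fell into 3 sets, A, B and C, that the labels do not record. Of the 12 non-lesional arrays, 2 were in set A, 2 in set B and 8 in set C, whereas every lesional array was in set A or B.

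Lesional was first compared with non-lesional skin before treatment, which gives the disease profile against which treatment was read, in the 13 lesional and 7 non-lesional biopsies of the dupilumab arms. Antimicrobial genes of the IL-17/IL-22 axis and genes of cell division were higher in lesional skin. The 17 antimicrobial and IL-17/IL-22 genes rose by a mean of 3.30 (adjusted p = 0.0409 with an estimated correlation between genes) and 12 of them passed on their own, 13 adjusted over the list alone. Among them were S100A8 and S100A9, the subunits of calprotectin, at 3.71 ± 0.53 (adjusted p = 4.36e-05) and 4.95 ± 0.76 (adjusted p = 9.8e-05), and psoriasin, S100A7, at 1.87 ± 0.27. The 14 proliferation genes rose by a mean of 1.73 (adjusted p = 0.00493 with an estimated correlation), 13 of them on their own and 13 adjusted over the list alone. MKI67, which encodes the cycling-cell antigen Ki-67, averaged 9.24 ± 0.83 (SD, n = 13) in lesional and 6.40 ± 1.34 (SD, n = 7) in non-lesional skin, a difference of 2.90 ± 0.42 (adjusted p = 4.36e-05). The spindle protein gene NUSAP1 rose by 1.85 ± 0.26 and the mitotic kinase gene AURKA by 1.83 ± 0.26.

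Of 13345 genes, 1686 passed at an adjusted p under 0.05 in limma, 1086 higher and 600 lower in lesional skin. The largest rises among them were of S100A7A, an antimicrobial paralog of S100A7, at 7.15 ± 1.40, the serine protease inhibitor SERPINB4 at 6.45 ± 1.38, IGFL1 at 6.13 ± 0.96 and the collagenase MMP1 at 5.43 ± 1.27, which was near the GCRMA floor in non-lesional skin. The elastase inhibitor PI3 rose by 3.96 ± 0.62, the neutrophil-associated S100A12 by 4.07 ± 1.05 from a non-lesional mean of 2.14 ± 0.28 (SD, n = 7) at that floor, the macrophage elastase MMP12 by 4.68 ± 1.44 and KRT16, a keratin of wounded and hyperproliferative epidermis, by 2.08 ± 0.48. IL4R, whose product dupilumab binds, averaged 11.28 ± 0.65 (SD, n = 13) against 9.95 ± 0.75 (SD, n = 7) and rose by 1.30 ± 0.28 (adjusted p = 0.00285). It was the 1 of 16 type 2 cytokine and receptor genes to pass over all genes, with 4 higher and 1 lower adjusted over the list alone, the others being the receptor genes IL7R, CRLF2 and TNFRSF4 (higher) and the Th2 and keratinocyte transcription factor GATA3 (lower). The largest falls were of the xenobiotic-metabolizing cytochrome CYP1A2 at -3.22 ± 0.52, the heparan sulfate sulfotransferase HS3ST6 at -2.81 ± 0.72, OPRPN, the opiorphin precursor, at -2.88 ± 0.87, the water and glycerol channel AQP9 at -2.63 ± 0.87 and WDR72 at -2.63 ± 0.88. The NCBI Gene identifiers are 6279 for S100A8, 6280 for S100A9, 4288 for MKI67, 5266 for PI3, 3566 for IL4R and 1544 for CYP1A2. In the GRCh38.p14 build, S100A9 lies on chromosome 1 from 153357854 to 153361023, MKI67 on chromosome 10 from 128096659 to 128126423, PI3 on chromosome 20 from 45174902 to 45176544 and IL4R on chromosome 16 from 27313756 to 27364778.

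Another 5 lists passed with the preset correlation and not with an estimated one. Interferon and Th1 genes had a mean difference of 1.85 (adjusted p = 3.15e-05 with the preset and 0.432 with an estimated correlation). Of the 13, 5 rose, 11 adjusted over the list alone, among them OASL of the antiviral response by 4.46 ± 0.82 and the CXCR3 ligands CXCL10 and CXCL9 by 4.55 ± 1.09 and 4.04 ± 1.18. The 14 T cell markers averaged 1.13 (adjusted p = 0.0175, and 0.726 with an estimated correlation), and the checkpoint receptor CTLA4, the costimulator ICOS and the T cell receptor subunit CD3D rose by 2.63 ± 0.80, 2.35 ± 0.76 and 1.43 ± 0.49. The 12 dendritic cell markers averaged 0.96 (adjusted p = 0.03, and 0.726 with an estimated correlation) with 4 rises, 6 rises and 1 fall adjusted over the list alone, including the homing receptor CCR7 by 2.20 ± 0.61 and the maturation markers CD86 and CD83 by 1.36 ± 0.42 and 1.49 ± 0.47. The 19 differentiation and junction genes averaged -0.52 (adjusted p = 0.000924, and 0.567 with an estimated correlation), of which the tight junction genes CLDN23 and CLDN1 fell, at -0.88 ± 0.19 and -0.80 ± 0.24. The 7 mast cell and basophil markers averaged -0.49 (adjusted p = 0.0224, and 0.491 with an estimated correlation), of which the stem cell factor receptor KIT and the transcription factor GATA2 fell, at -0.84 ± 0.22 and -0.82 ± 0.23. Counts for the last 3 of these lists, T cells, differentiation and mast cells, were 3, 2 and 2 adjusted over the list alone, as over all genes. The dendritic call was lost without any 1 of 8 patients (adjusted p from 0.0556 to 0.165). Without one 300 mg patient the T cell and mast cell calls were lost too (adjusted p = 0.13 and 0.0621).

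The remaining 15 lists did not pass. Type 2 cytokines and receptors averaged 0.52 (adjusted p = 0.12), type 2 chemokines with IL-4/IL-13 response genes 1.02 (0.125), macrophage markers 0.63 (0.0952), eosinophil and neutrophil markers 1.24 (0.131), B and plasma cell markers 1.16 (0.484), hair follicle genes 0.77 (0.653), fibroblast markers 0.13 (0.66) and housekeeping genes 0.07 (0.84). Sebaceous gland genes averaged -0.68 (0.242), melanocyte markers -0.23 (0.398), endothelial markers -0.17 (0.352), adipocyte markers -0.30 (0.629) and muscle markers -0.47 (0.305). Signs differed within a pair of lists. The 13 barrier lipid genes had a mean of -0.02, a median of 0.16 and an upward test statistic (0.863), and the 6 eccrine gland markers a mean of 0.09, a median of 0.29 and a downward one (0.773). Single members of lists that did not pass were the macrophage marker AIF1, which rose by 1.27 ± 0.32, the glucosylceramide synthase gene UGCG, which rose by 0.60 ± 0.19, and the melanocyte and Schwann cell transcription factor SOX10, at -1.28 ± 0.36. Adjusted over the list alone, MARCO of the macrophage list, CLC, CXCR2 and FPR1 of the eosinophil and neutrophil list and HPRT1 of the housekeeping list were also higher. The housekeeping gene PPIA was higher by 0.24 ± 0.08 (adjusted p = 0.0367), which did not pass after further quantile normalization (0.0551) or centring of arrays (0.321). Among panel genes, the CCR4 ligands CCL22 and CCL17 had differences of 1.68 ± 0.62 and 2.75 ± 1.08 (adjusted p = 0.0662 and 0.085), the cornified envelope gene LORICRIN -1.26 ± 0.58 (0.143), the tight junction gene CLDN8 -1.27 ± 0.57 (0.134), CCL18 1.16 ± 0.73 (0.297), CCL26, or eotaxin-3, 1.52 ± 1.13 (0.39), the receptor subunit IL13RA1 0.19 ± 0.17 (0.477) and filaggrin, FLG, -0.31 ± 0.32 (0.542), none of which passed.

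This comparison depended on the array sets. With the array set as a fixed term, added after the data were examined, 122 genes passed, 97 higher and 25 lower, all of them among the 1686. The proliferation shift was then 1.58 (adjusted p = 0.0298 with an estimated correlation) and the antimicrobial shift 3.06 (adjusted p = 0.132 with an estimated correlation), while IL4R and KRT16 no longer passed (adjusted p = 0.0699 and 0.117). With the preset correlation the set term also ended the calls of dendritic cell markers (0.83, adjusted p = 0.117) and mast cell markers (-0.29, adjusted p = 0.155), with CCR7, CD86, CD83, KIT and GATA2 at adjusted p from 0.128 to 0.277, and macrophage markers passed (0.77, adjusted p = 0.02, and 0.657 with an estimated correlation). Of the 7 patients with both biopsies, 3 had them in one set. In those pairs the antimicrobial genes differed by 3.00 ± 2.66 (SD) and the proliferation genes by 1.49 ± 1.06 (SD), against 3.66 ± 2.17 and 1.69 ± 0.89 (SD) in the 4 pairs across sets. Both lists were higher in lesional skin in 7 of 7 pairs, where the exact sign-flip p of 0.0156 is the smallest possible, and 0.0859 adjusted over the lists. With the patient block as a fixed effect 723 genes passed, and with array weights 5672. The count was 559 without one 150 mg patient, 1022 without another 150 mg patient and 1047 without one 300 mg patient. Of the 1686 genes 64.4% were higher in lesional skin as deposited, 60.6% of 1905 after further quantile normalization and 45.7% of 1867 after centring of arrays, which moved the median of all genes by -0.10.

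**Figure D1:**
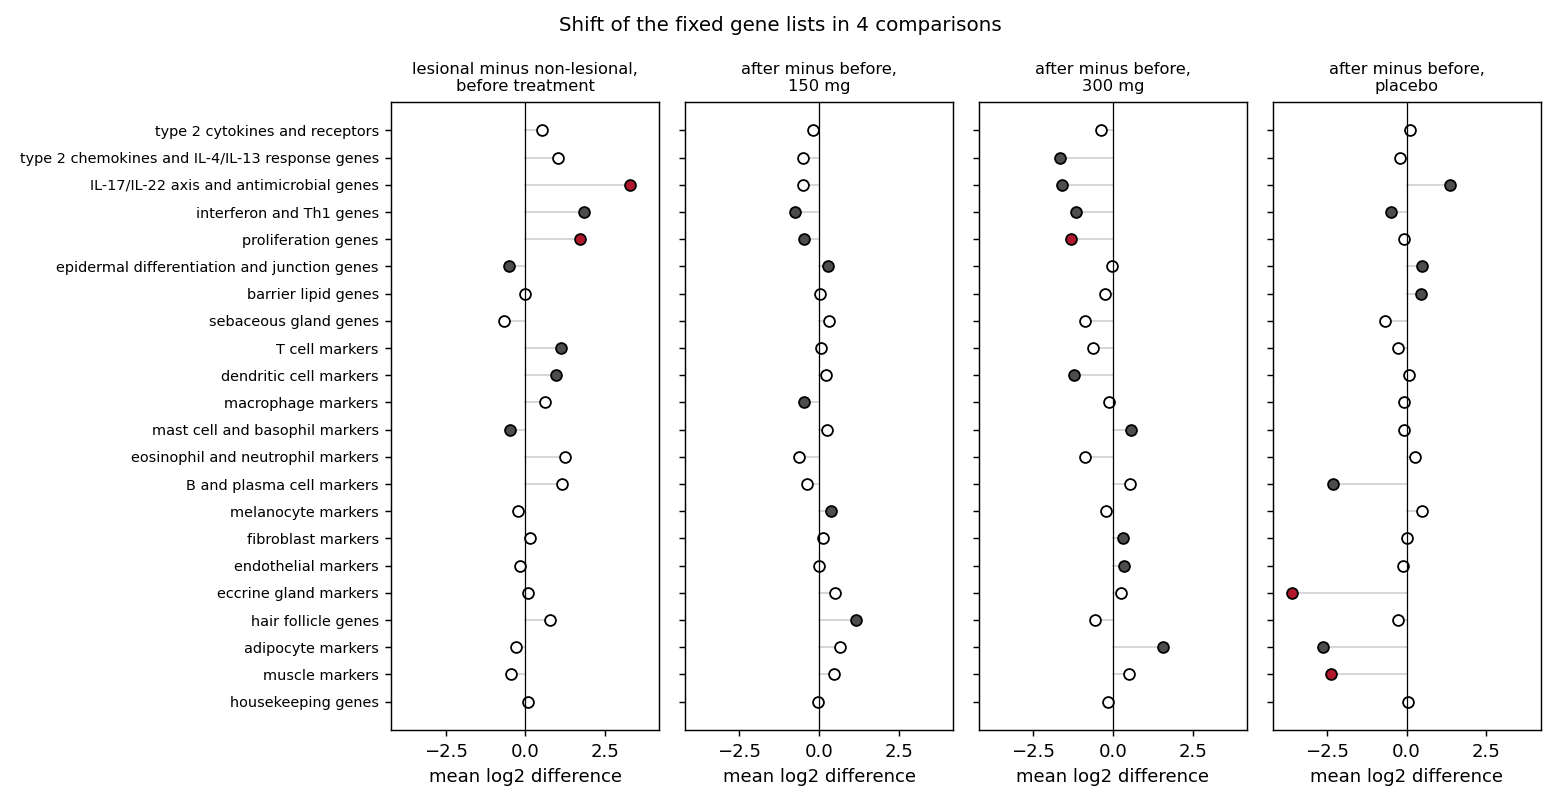
Each point is the mean log2 difference of one of the 22 gene lists, in lesional against non-lesional skin before treatment and in lesional skin after against before 150 mg, 300 mg and placebo. Red points passed at an adjusted p under 0.05 with an estimated correlation between genes, grey points with the preset correlation alone and white points with neither; proliferation genes are red at 1.73 before treatment and -1.31 after 300 mg.

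Lesional skin after dupilumab was compared with lesional skin before it, to ask which disease genes changed on treatment, first with both doses together. Proliferation genes fell by 0.89 (adjusted p = 0.0465 with an estimated correlation between genes), with all 14 lower, 14 adjusted over the list alone and 0 over all genes. In the 9 paired patients their mean change was -0.76 ± 0.84 (SD), downward in 8 of 9, with an exact sign-flip p of 0.0117 and 0.129 adjusted over the lists. Both biopsies of each pair were in one array set. The change was -0.24 ± 0.35 (SD, 3 of 4 pairs lower) in set A and -1.18 ± 0.91 (SD, 5 of 5 lower) in set B. CDCA5, needed for sister chromatid cohesion, had a change of -1.37 ± 0.29 (adjusted p = 0.118) and MKI67 of -1.15 ± 0.38 (adjusted p = 0.24), neither passing alone.

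Type 2 chemokines with IL-4/IL-13 response genes averaged -1.08 at both doses, with 9 of 9 genes lower, CCL26 alone passing when adjusted over the list alone (list adjusted p = 0.00461 with the preset and 0.498 with an estimated correlation). Their paired change was -0.85 ± 1.20 (SD, n = 4) in set A and -1.12 ± 1.11 (SD, n = 5) in set B, lower in 7 of 9 pairs (exact sign-flip p = 0.0352, and 0.243 adjusted over the lists). CCL26, the eosinophil attractant, had a change of -3.44 ± 1.02 (adjusted p = 0.187) and was lower in 8 of 9 pairs, CCL18 of -1.53 ± 0.66 (0.355) and CCL17 of -1.47 ± 0.97 (0.6). Type 2 cytokines and receptors averaged -0.29 (adjusted p = 0.305); 1 of the 16, IL13RA2, the IL-13 decoy receptor, passed adjusted over the list alone, at -2.78 ± 0.76 (adjusted p = 0.142 over all genes). Antimicrobial and IL-17/IL-22 genes averaged -1.04 (adjusted p = 0.00383, and 0.59 with an estimated correlation), but -0.50 without one 300 mg patient (adjusted p = 0.246), with paired changes of -0.19 ± 1.66 (SD, n = 4) in set A and -2.29 ± 2.07 (SD, n = 5) in set B. Fitted to all arrays of set A alone, their shift at both doses turned to 0.37. Within the list PI3 had a change of -1.55 ± 0.56 (0.273), S100A12 of -2.96 ± 0.94 (0.225) and S100A7 of -0.06 ± 0.25 (0.966). S100A12 averaged 3.32 in lesional skin after dupilumab, under the filter level of 4, so the size of its change is uncertain here and at each dose. Interferon and Th1 genes averaged -0.95 (adjusted p = 0.000812, and 0.455 with an estimated correlation), with 0.01 ± 1.60 (SD, n = 4) in set A and -1.52 ± 0.71 (SD, n = 5) in set B.

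Adipocyte, mast cell and fibroblast markers passed with the preset correlation and a mean of the opposite sign, whereas T cell, dendritic cell, macrophage and sebaceous gland genes, which did not pass, averaged -0.29, -0.49, -0.30 and -0.29. In the 9 pairs, however, sebaceous gland genes averaged 0.69 ± 1.15 (SD, 7 of 9 higher) and T cell markers 0.00 ± 1.29 (SD). Adipocyte markers averaged 1.12 (adjusted p = 0.0159, and 0.59 with an estimated correlation), higher in 8 of 9 pairs (exact sign-flip p = 0.0117, and 0.129 adjusted over the lists), with 1.46 ± 0.36 (SD, n = 4) in set A and 1.22 ± 1.34 (SD, n = 5) in set B; without one 300 mg patient the mean was 0.89 (adjusted p = 0.0754). Mast cell markers averaged 0.41 (adjusted p = 0.00237, and 0.365 with an estimated correlation) and fibroblast markers 0.23 (adjusted p = 0.000933, and 0.365 with an estimated correlation). In these 3 lists, and in the antimicrobial and interferon lists, 0 members passed adjusted over the list alone. No single gene passed in limma at both doses, and 1534 had an unadjusted p under 0.05, where 667 are expected by chance. The smallest p-values belonged to PEX3, of peroxisome assembly, at -0.93 ± 0.17 (adjusted p = 0.0505), PI16, a fibroblast-expressed peptidase inhibitor, at 2.37 ± 0.49 (0.118), CDCA5, NOP10 of the small nucleolar ribonucleoproteins at -0.66 ± 0.14 (0.118) and the splicing protein gene SNRPD1 at -0.61 ± 0.13 (0.118). The count was 43 with array weights and at most 3 in any refit without one patient.

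At 300 mg alone, proliferation genes fell by 1.31 (adjusted p = 0.0157 with an estimated correlation), with 14 of 14 lower and 13 adjusted over the list alone, in 3 of 3 pairs at -1.37 ± 1.24 (SD); the exact sign-flip p of 0.25 is the smallest that 3 pairs allow. Another 8 lists passed with the preset correlation only. Type 2 chemokines averaged -1.65 (adjusted p = 0.000925, and 0.404 with an estimated correlation), antimicrobial genes -1.58 (0.000925, and 0.404), interferon genes -1.14 (0.00299, and 0.404) and dendritic cell markers -1.21 (0.000675, and 0.404). Mast cell markers averaged 0.58 (0.00144, and 0.282), fibroblast markers 0.33 (0.000581, and 0.282), endothelial markers 0.35 (0.0142, and 0.404) and adipocyte markers 1.58 (0.00818, and 0.404). None of these 8 lists had a member that passed adjusted over the list alone. The antimicrobial shift was -0.49 without one 300 mg patient (adjusted p = 0.476) and 0.63 within array set A, and the adipocyte shift was 1.12 without another 300 mg patient (adjusted p = 0.0811). The endothelial call was lost without any 1 of 3 300 mg patients (adjusted p from 0.0668 to 0.16). Without one 300 mg patient the fibroblast shift was 0.18.

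PEX3 was the 1 gene to pass at 300 mg, at -1.49 ± 0.25 (adjusted p = 0.0204, NCBI Gene 8504, chromosome 6 from 143450805 to 143490616), and 1008 genes had an unadjusted p under 0.05. Its call was lost without one 150 mg patient (adjusted p = 0.0876) and without any 1 of 4 300 mg patients (0.0505, 0.0834, 0.15 and 1.00). Over all probe sets of PEX3 the change was -0.56 (adjusted p = 0.336), and with the patient block as a fixed effect the adjusted p was 0.394. None of the 15 panel genes passed. S100A7 and IL4R, both higher in lesional skin before treatment, changed by -0.16 ± 0.37 and -0.29 ± 0.39, less than their errors. MKI67 averaged 9.18 ± 1.04 (SD, n = 6) before and 7.42 ± 0.84 (SD, n = 4) after, a change of -1.75 ± 0.57 (limma adjusted p = 0.44). PI3 averaged 14.10 ± 0.63 and 11.61 ± 2.16 (SD), MMP12 10.83 ± 1.93 and 5.88 ± 3.45 (SD) and CCL26 7.59 ± 1.81 and 3.42 ± 0.40 (SD), with changes of -2.52 ± 0.85, -5.06 ± 1.98 and -4.26 ± 1.55 (adjusted p = 0.459, 0.547 and 0.53). The CCL26 mean after treatment lay under the filter level of 4, near the GCRMA floor, so the size of its change is uncertain. S100A12 had a change of -3.51 ± 1.44, CCL17 of -3.39 ± 1.48, CCL18 of -1.87 ± 1.00 and KRT16 of -0.88 ± 0.65. Over both doses S100A12 averaged 3.32 after treatment, also under the filter level, so the size of its change is uncertain too. Sebaceous gland genes had a mean of -0.89 over all arrays but 1.06 ± 1.63 (SD) in the 3 pairs.

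At 150 mg, 6 lists passed with the preset correlation and 0 with an estimated one. Interferon genes averaged -0.77 (adjusted p = 0.00363, and 0.614 with an estimated correlation), proliferation genes -0.46 (0.000731, and 0.614), macrophage markers -0.48 (0.0101, and 0.614), differentiation and junction genes 0.28 (0.0241, and 0.642), melanocyte markers 0.36 (0.0292, and 0.614) and hair follicle genes 1.14 (0.0241, and 0.642). All 14 proliferation genes were lower, and the paired change was downward in 5 of 6 patients (exact sign-flip p = 0.0938). None of the 6 lists had a member that passed adjusted over the list alone. Each call but that of proliferation genes was lost in at least 2 of the refits without one patient. Without one 150 mg patient the shifts were -0.46 for interferon genes, -0.22 for macrophage markers, 0.15 for differentiation genes and 0.28 for hair follicle genes (adjusted p = 0.139, 0.215, 0.225 and 0.454). Without another 150 mg patient the melanocyte shift was 0.18 (adjusted p = 0.218). Within array set A the direction turned in 4 of the 6, with interferon genes at 0.52, differentiation genes at -0.0419, macrophage markers at 0.0175 and hair follicle genes at -0.17. No single gene passed in limma, and 478 had an unadjusted p under 0.05. CCL26 had a change of -2.62 ± 1.32, S100A12 of -2.40 ± 1.22, CCL18 of -1.19 ± 0.85, CLDN8 of 0.90 ± 0.66, PI3 of -0.58 ± 0.73 and MKI67 of -0.55 ± 0.49 (limma adjusted p = 1.00 for each). The smallest p-values belonged to the folate transporter gene SLC46A1 (0.64 ± 0.17), the exon junction gene RBM8A (-0.64 ± 0.17), ZNF493 (0.74 ± 0.20), VCPIP1 (-1.05 ± 0.29) and METTL6 (-0.99 ± 0.29), none passing.

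**Figure D2:**
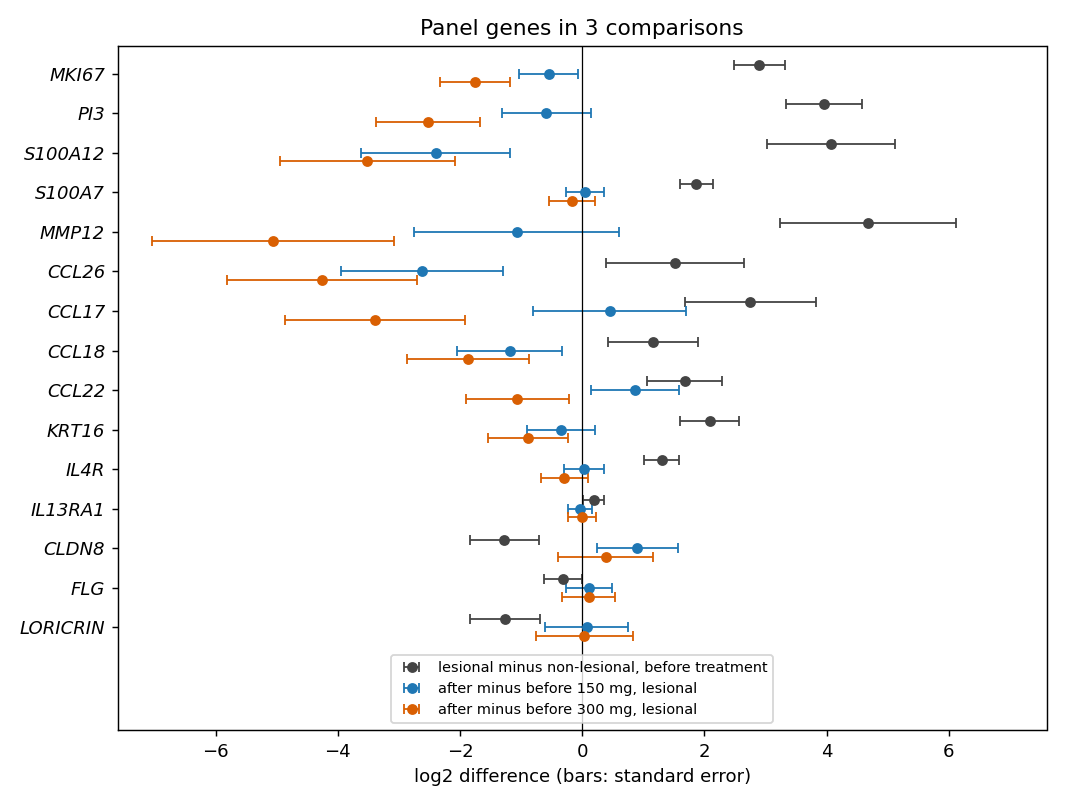
Points are the log2 difference of each measured panel gene and bars its standard error, for lesional minus non-lesional skin before treatment (grey) and for lesional skin after minus before 150 mg (blue) and 300 mg (orange). PI3 lies at 3.96 before treatment and at -2.52 after 300 mg, S100A7 at 1.87 and -0.16; no treatment difference shown passed over all genes.

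The lesional signature score summarizes the disease profile in one value per biopsy. At 150 mg it averaged 2.42 ± 0.76 (SD, n = 7) in lesional skin before and 1.86 ± 0.77 (SD, n = 6) after treatment, against -0.42 ± 1.24 (SD, n = 3) in non-lesional skin before it. The paired change was -0.62 ± 0.85 (SD), downward in 4 of 6 patients (exact two-sided sign-flip p = 0.125), and the group means moved by 19.7% of the gap to non-lesional skin. At 300 mg it averaged 2.35 ± 0.74 (SD, n = 6) before and 0.98 ± 0.80 (SD, n = 4) after, against 0.02 ± 0.43 (SD, n = 4) in non-lesional skin, or 58.7% of the gap. The paired change was -1.70 ± 1.28 (SD) in 3 of 3 patients (exact p = 0.25, the smallest possible), or -0.96 without one 300 mg patient. With all biopsies taken as unpaired the exact permutation p was 0.0333. That test ignores that 3 patients are in both groups, so its p is only approximate. Over both doses the paired change was -0.98 ± 1.07 (SD), downward in 7 of 9 patients (exact sign-flip p = 0.0195, 0.0586 adjusted over the 3 sign-flip tests of each dose and both together, and 0.0977 over all 5 sign-flip tests, those within array sets included). It was -0.26 ± 0.84 (SD, 2 of 4 patients lower, exact p = 0.625) within array set A and -1.55 ± 0.92 (SD, 5 of 5 lower, exact p = 0.0625, the smallest possible) within set B. Without either of 2 300 mg patients the exact p was 0.0547 or 0.0625. The signatures from the 2 arms shared 74 of their 200 higher and 52 of their 200 lower genes, where 3.00 are expected for independent genes and arms. Genes that vary together and the adjustment between array sets break that assumption, so the overlap is no test of replication between the arms.

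**Figure D3:**
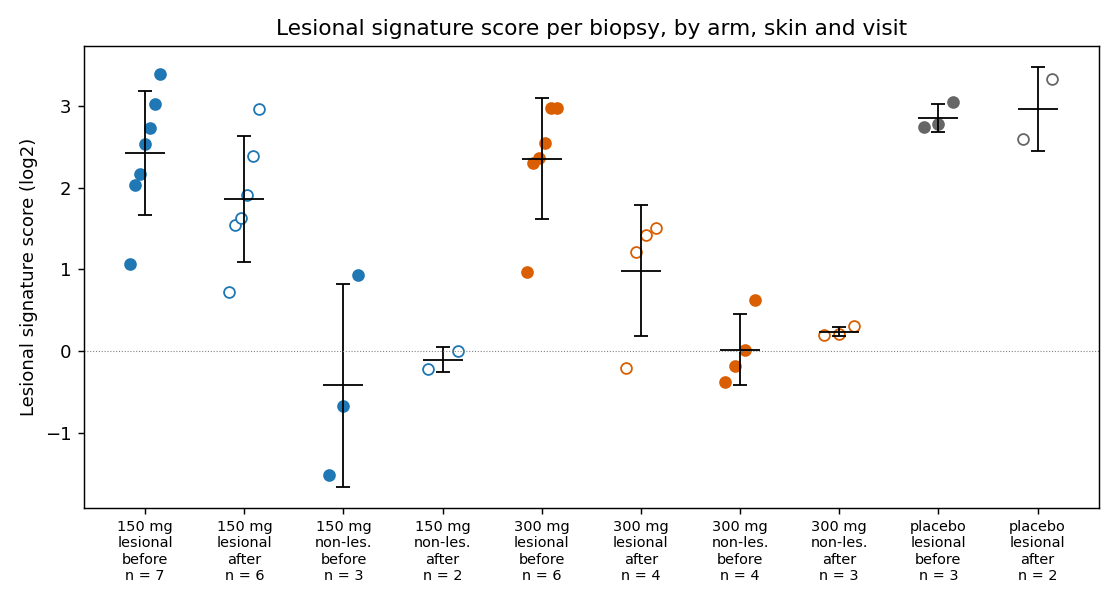
Each point is one biopsy's lesional signature score, the mean log2 value of 200 genes higher in lesional skin minus that of 200 lower ones, by arm, skin and visit, with horizontal lines at group means and bars of 1 SD. Lesional means are 2.42 and 1.86 before and after 150 mg, 2.35 and 0.98 before and after 300 mg, and 2.85 and 2.96 before and after placebo.

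Under placebo, lesional skin after was compared with lesional skin before, as the reference for change without the drug, in 3 biopsies before and 2 after with 1 pair among them. The signature score averaged 2.85 ± 0.17 (SD, n = 3) before and 2.96 ± 0.51 (SD, n = 2) after (exact permutation p = 0.8, smallest possible 0.1). Eccrine sweat gland markers had a mean change of -3.60 (adjusted p = 0.000104 with an estimated correlation), 4 of 6 (DCD, SCGB1D2, SCGB2A2 and PIP) passing adjusted over the list alone, but 0.43 without one placebo patient. Muscle markers fell by 2.36 (adjusted p = 0.00103 with an estimated correlation), 4 of 5 adjusted over the list alone (MYH11, ACTG2, DES and ACTA1, of smooth and skeletal muscle), and by 2.02 to 2.97 in the refits without one patient. Adipocyte markers had a mean of -2.62 (adjusted p = 3.6e-08, and 0.0648 with an estimated correlation), 1 of 7 (FABP4) passing adjusted over the list alone, but 0.08 without the same patient. B and plasma cell markers averaged -2.30 (0.00057, and 0.101 with an estimated correlation), antimicrobial genes 1.38 (0.00019, and 0.539; CCL20 alone higher adjusted over the list alone), interferon genes -0.49 (0.00219, and 0.563), differentiation genes 0.47 (0.00958, and 0.642) and barrier lipid genes 0.45 (0.0204, and 0.576). Each of these 5 calls was lost without at least one placebo patient, with 0.18 for antimicrobial genes, 0.43 for interferon genes, -0.15 for differentiation genes, -0.03 for barrier lipid genes and -1.41 for B and plasma cell markers. No gene passed in limma, and 130 had an unadjusted p under 0.05. With the patient block as a fixed effect 8 passed, all lower, which rest on the 1 patient with both biopsies. The smallest p-values belonged to the bradykinin receptor BDKRB1 at 1.27 ± 0.25 (adjusted p = 0.159), DCD, which encodes the sweat peptide dermcidin, at -5.85 ± 1.31 (0.502), the CCR6 ligand CCL20 at 5.48 ± 1.25 (0.502; near the floor before placebo), SCGB2A2 at -5.60 ± 1.31 (0.547) and STXBP4 at 1.07 ± 0.33 (1.00). Without one placebo patient 10 genes passed.

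The doses were compared by the difference of their changes in lesional skin, 300 mg minus 150 mg, which tests a dose response. Proliferation genes differed by -0.84 (adjusted p = 2.88e-08 with the preset and 0.354 with an estimated correlation) and dendritic cell markers by -1.44 (1.47e-06, and 0.513). With the preset correlation 9 lists passed and with an estimated one 0, and 0 members of any of the 9 passed adjusted over the list alone. In the paired patients an exact permutation test of each list between doses gave a smallest p of 0.0714, 0.655 adjusted over the lists. No gene passed in limma (183 at an unadjusted p under 0.05), with differences of -1.20 ± 0.75 for MKI67, -3.84 ± 1.94 for CCL17 and -1.93 ± 1.12 for PI3. The smallest p-values belonged to DNM3 (1.76 ± 0.43), GLRX2 (-0.95 ± 0.25), GJA3 (-2.40 ± 0.64), LINC00491 (2.45 ± 0.70) and PEX3 (-1.13 ± 0.33), all at an adjusted p of 1.00. The signature change differed by -1.08 (exact two-sided permutation p = 0.238, smallest possible 0.0119), so a larger change at 300 mg was not resolved.

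Dupilumab was compared with placebo by the difference of their changes. Eccrine gland and muscle markers differed by 3.97 and 2.85 (adjusted p = 0.00384 and 0.00735 with an estimated correlation), with 5 of 6 (the 4 named under placebo and AQP5) and 4 of 5 members (as under placebo) passing adjusted over the list alone; without one placebo patient the eccrine difference was -0.06 (adjusted p = 0.737). Antimicrobial and IL-17/IL-22 genes differed by -2.42 (adjusted p = 4.25e-06, and 0.299 with an estimated correlation; CCL20 alone lower adjusted over the list alone) and proliferation genes by -0.80 (0.000709, and 0.423; 0 adjusted over the list alone), which became -1.21 and -0.36 without one placebo patient (0.108 and 0.371). Within array set A these differences were positive, at 0.19 and 0.0674, and the eccrine difference was -0.28. With the preset correlation 10 lists passed and with an estimated one 2. No gene passed in limma (389 at an unadjusted p under 0.05), though some did without one placebo patient. With the patient block as a fixed effect 8 passed, all higher, which rest on 1 placebo pair. The smallest p-values belonged to BDKRB1 (-1.29 ± 0.27, adjusted p = 0.523), DCD (5.98 ± 1.44), CCL20 (-5.70 ± 1.38), SCGB2A2 (5.81 ± 1.45) and the epidermal growth factor family member HBEGF (-2.91 ± 0.75). The placebo arm's 5 arrays limit this comparison, and centring of arrays moved its median over all genes by 0.13. It therefore does not separate the fall of proliferation genes after dupilumab from change over time.

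After dupilumab, lesional skin was compared with non-lesional skin, 10 biopsies against 5, to show what remained of the disease profile. In limma 97 genes passed, 46 higher and 51 lower, and 5 passed with the patient block as a fixed effect. The 1686 genes before treatment came from 13 against 7 biopsies, spread otherwise over the array sets. The counts therefore do not measure how much of the profile remained. FBN2, a microfibril component, rose by 2.97 ± 0.57 (adjusted p = 0.00948), the EGFR pathway gene FAM83A by 2.66 ± 0.56, NIBAN3 by 3.21 ± 0.80, FCHSD1 by 2.61 ± 0.65 and SPATA6L by 2.39 ± 0.56. Falls were of DKK1, a secreted Wnt inhibitor, at -3.04 ± 0.58 (adjusted p = 0.00948; near the floor in lesional skin), CCDC15 at -2.10 ± 0.36, ZNF551 at -2.08 ± 0.39, MYCL at -2.25 ± 0.49 and CNTNAP3P2 at -2.69 ± 0.62. S100A7 differed by 1.24 ± 0.32 (0.0554), MKI67 by 0.72 ± 0.49 (0.516), PI3 by 0.85 ± 0.74 (0.627) and CCL26 by -2.91 ± 1.34 (0.293). With the array set as a fixed term 0 genes passed. The count was 61 without the biopsy whose title and tag disagree, which is in neither group and acts only through the shared fit. It was 0 and 43 without one or another 150 mg patient, 207 without a further 150 mg patient, 8, 33, 50 or 62 without 300 mg patients and 52 without one placebo patient. Of the 97 genes 47.4% were higher, against 59.3% of 135 after further quantile normalization. Of the 5 pairs, 1 had both biopsies in one set, so sets and tissues were not separable within pairs.

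In non-lesional skin after against before dupilumab, 5 biopsies against 7, no gene passed in limma and 103 had an unadjusted p under 0.05. MKI67 had a change of 1.03 ± 0.52, PI3 of 1.56 ± 0.78 and S100A7 of 0.57 ± 0.34 (adjusted p = 1.00 for each). The smallest p-values belonged to LOC105372069 (1.64 ± 0.47), NELL1 (1.38 ± 0.44), NT5DC1 (0.56 ± 0.19), IMP3 (0.45 ± 0.15) and NPTX1 (-2.21 ± 0.81).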

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

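Tests of the array sets, of the antimicrobial and proliferation lists, of dilution by fat and dermis, of the set against the size of the fall, and of the placebo list shifts without one patient were chosen only after their results were seen, as were the pooled signature test over both doses and the use of unadjusted counts in the splits. Their p-values are nominal, and about 10 tests of the signature score were made in all.

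The first pattern is the difference between lesional and non-lesional skin before treatment. If shifts between the array sets were its whole cause, the antimicrobial and proliferation lists would lose their shift with the set as a term. The smaller of the shares they kept was 91.4%, which cannot decide the question, for the reason given below. With that term and an estimated correlation the antimicrobial call was lost, while the proliferation call stayed. The drop from 1686 to 122 genes came with a median size of 0.91 log2 before and 0.89 after, and with a median standard error of 0.24 before and 0.32 after, so mainly the error grew. Over 3043 probe sets at the floor, non-lesional arrays before treatment in sets A and B differed from those in set C in proportion to the shift of set B (r = 0.995, slope 0.335). With set C so aligned, the set term could hardly move the size. The kept size is therefore no separate support for these lists or for the 1686 genes. A shift shared by a set cancels in the 3 pairs that lay within one set. There the antimicrobial genes differed by 3.00 ± 2.66 (SD) and the proliferation genes by 1.49 ± 1.06 (SD), both higher in 3 of 3. In those pairs this argues against set shifts as the whole cause. The alignment of array set C to the others may still have narrowed the spread among non-lesional arrays, since 2.86% of the 35 splits of those arrays, 1 split, had as small a median difference (0.10, against 0.24 for the median split). Of 100 splits that swapped labels within pairs, 1 gave 1686 genes, the real one, and the highest of the others, which relabelled 1 pair, gave 1237. The real labels thus gave more genes than any other split tried. In the 4 of 7 pairs that lay across array sets the splits swapped set and tissue together. An alignment that narrowed the spread of the real non-lesional group would by itself favour the real labels. The splits therefore do not tell the tissue from the array sets as the source of the count. The biological explanation, the disease itself, stays open beside the spread.

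The second pattern is the fall of proliferation genes and of the lesional signature after dupilumab, where more fat and dermis in the second biopsy would lower epidermal genes alike. Over the 9 pairs proliferation genes changed by -0.76 and differentiation genes by 0.29, a difference of -1.05 ± 1.12 (SD, 7 of 9, exact sign-flip p = 0.0234). Over the pooled pairs this argues against a dilution that lowers both lists alike as the whole cause. It rests on array set B (-1.18 ± 0.91 and 0.57 ± 0.35, SD, n = 5), while in set A (-0.24 ± 0.35 and -0.06 ± 0.45, SD, n = 4) dilution stays open. A dilution hidden by a separate rise of differentiation genes was not tested. The fall of the signature score was larger in array set B than in set A (exact permutation p = 0.0317), so the set, or the patients who happen to be in it, may set the size of that fall; proliferation genes were not tested between the sets. A change over time without the drug stays open, since the placebo arm gave an exact p of 0.8 with 0.1 the smallest possible. Among 100 splits of the pairs 7 gave as many genes at an unadjusted p under 0.05 as the real 1534, the highest other 1995, so a random grouping cannot be excluded for the gene count.

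The third pattern is the lower level of gland, muscle and fat markers after placebo. If the tissue content of one biopsy were the cause, the shifts would vanish without one patient. Eccrine gland markers went to 0.4344 and adipocyte markers to 0.0796 without the patient whose removal moved them most. These equal the shifts within array set A, since that patient held both placebo arrays of set B. A shift shared by set B cancels between the before and after biopsies of that patient. In the 5 dupilumab pairs of set B, eccrine gland markers changed by 0.63 ± 0.83 (SD) and adipocyte markers by 1.22 ± 1.34 (SD), each higher in 4 of 5. For these markers this argues against the array set as the cause. The content of a single biopsy and a change in that patient can not be told apart. Muscle markers stayed at -2.0206 or below without any one patient, which argues against one biopsy as their cause. With 5 placebo arrays the depth of several biopsies and a change over time were not tested apart.

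Single arrays stood far from the rest of their group in 17 of 190 groups of 4 to 7 arrays, screened over the 22 list scores, the signature score and the 15 panel genes, where chance gives about 1 in 20. That rate assumes independent groups of normally distributed values, whereas panel genes also belong to lists, so 17 of 190 is no test against it. Each value is the gap to the nearest other array as a share of the group's range. Where most arrays of a group lie near the GCRMA floor, 1 brighter array gives a share near 1. This may hold for S100A12, which averaged 3.32 in lesional skin after dupilumab. In lesional skin before 150 mg the lowest array lay apart in interferon genes (0.579). In lesional skin before 300 mg the highest lay apart in B and plasma cell markers (0.639), and the lowest in adipocyte markers (0.683), the signature score (0.662), CCL18 (0.724) and S100A7 (0.848). In lesional skin after 150 mg the highest lay apart in type 2 chemokines (0.661), CCL26 (0.788) and S100A12 (0.952). In lesional skin after 300 mg the highest lay apart in CCL17 (0.919) and S100A12 (0.994), and the lowest in S100A7 (0.924). In non-lesional skin before 300 mg the highest lay apart in type 2 chemokines (0.848), CCL26 (0.946), S100A7 (0.91) and MMP12 (0.941), and the lowest in macrophage markers (0.888).

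The change in lesional skin differed between doses, 300 mg minus 150 mg, in 9 lists with the preset correlation. The differences were -1.16 for type 2 chemokines, -1.08 for antimicrobial genes, -0.84 for proliferation genes, -1.20 for sebaceous gland genes, -1.44 for dendritic cell markers, -0.57 for melanocyte markers, 0.21 for fibroblast markers, 0.34 for endothelial markers and -1.70 for hair follicle genes. With an estimated correlation their adjusted p ran from 0.354 to 0.603, and every call but that of dendritic cell markers moved by over 1.5 times or was lost without at least one patient. In the paired patients the sebaceous difference had the opposite sign, 0.56 (0.50 at 150 mg and 1.06 at 300 mg), and within array set B it was 2.27. Without one 300 mg patient the antimicrobial difference was 0.0069, and within array set A it was 0.52 and the fibroblast difference -0.12.

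The change differed between dupilumab and placebo in 10 lists with the preset correlation. The differences were -2.42 for antimicrobial genes, -0.80 for proliferation genes, -0.57 for barrier lipid genes, 0.50 for mast cell markers, 2.38 for B and plasma cell markers, 0.22 for fibroblast markers, 0.29 for endothelial markers, 3.97 for eccrine gland markers, 3.73 for adipocyte markers and 2.85 for muscle markers. With an estimated correlation the eccrine and muscle differences passed (adjusted p = 0.00384 and 0.00735), the adipocyte difference had an adjusted p of 0.0648, and the other 7 ran from 0.299 to 0.483. Without one placebo patient the adipocyte difference was 1.04, the eccrine one -0.06, the antimicrobial one -1.21, the proliferation one -0.36 and that of B and plasma cell markers 1.49. Without another placebo patient the barrier lipid difference was -0.085, that of mast cell markers 0.085, of fibroblast markers -0.0014 and of endothelial markers 0.11. Of these 9 differences none passed in those refits. Within array set A the antimicrobial, proliferation and eccrine differences were 0.19, 0.0674 and -0.28, and within set B the barrier lipid, mast cell and fibroblast differences were 0.33, -0.11 and -0.0844.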

How the results depend on the processing

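The alternatives with array sets, as a term, within a set, without set C or in the signature's source, were chosen only after the data were examined; all others were planned and run. Of 599 counts and score changes under an alternative, 508 stayed within 1.5 times the reported count or, for scores, on the same side of the threshold, 59 were weaker and 32 stronger; a count that stayed can still differ in its split, as in the 853 higher and 1014 lower genes of lesional skin before treatment after centring of arrays, against 1086 and 600. Of 6902 values of single genes 6470 were counted as unchanged, 381 as weaker, 51 as stronger and 0 as reversed, and of 4994 list shifts 4626, 207, 131 and 30. A reversal was counted only for values that passed as reported. Values that did not pass could change sign and still count as unchanged. The GCRMA floor limits dim probe sets, whose differences below it cannot be seen. Except where the alternative tested fewer arrays or genes, the cause of a change was not tested.

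For lesional against non-lesional skin before treatment (1686 genes), 723 passed with the patient block as a fixed effect, 1410 with no block, all among the 1686, 5672 with array weights, 735 at 2-fold or more, 1071 with only the groups compared in the fit, 122 with the array set as a term, 8 with the set term and fixed block together, 14 within set A and 47 without set C. Leaving out one patient at a time gave 559 to 1936 genes and 4 to 10 lists, and an estimated correlation 2 lists. For the same comparison after dupilumab (97 genes), 41 passed with no block, 5 with a fixed block, 153 with no filter on dim probe sets, 192 with the mean of all probe sets, 2 with array weights, 61 without the biopsy whose title and tag disagree, 15 with only the groups compared and 0 with the set term. Leaving out one patient gave 0 to 207, and an estimated correlation 0 lists.

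At 300 mg, where PEX3 passed, 0 genes passed with a fixed block, the mean of all probe sets, array weights, only the groups compared, within set A or without set C, and within set B 1 other gene passed, higher after treatment. Leaving out one patient gave 0 to 1, and an estimated correlation 1 list. At both doses 1 gene passed with the stricter filter, 1 after quantile normalization, 43 with array weights and 1 within set B. Leaving out one patient gave 0 to 3 genes and 6 to 11 lists, and an estimated correlation 1 list. At 150 mg an estimated correlation gave 0 lists, and leaving out one patient 2 to 9.

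Under placebo 5 genes passed with no filter and 2 with array weights. With a fixed block 8 passed, but only the 1 placebo patient with both biopsies informs that change. Sets A and B each held 1 placebo array after treatment, so gene counts within a set are not given. Leaving out one patient gave 4 to 10 lists, and can leave a single placebo array assumed to vary like the other groups. An estimated correlation gave 2 lists and set A alone 5. For dupilumab minus placebo 4 genes passed with no filter. With a fixed block 8 passed, which again rest on 1 placebo pair. Lists ran from 6 to 10 without one patient, with 2 under an estimated correlation. For the dose difference 1 gene passed with array weights, 1 within set A and 1 within set B; 5 lists passed with no filter, 0 with an estimated correlation, 4 within set A and 4 to 11 without one patient. In non-lesional skin lists ran from 4 to 8 without one patient, with 0 under an estimated correlation.

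Single list shifts that passed as reported with the preset correlation changed sign as follows. Sign changes of lists that did not pass are not covered here. Within set A at 150 mg, interferon genes were at 0.52, differentiation genes at -0.0419, macrophage markers at 0.0175 and hair follicle genes at -0.17. Within set A antimicrobial genes were at 0.63 at 300 mg, 0.37 at both doses, 0.52 for the dose difference and 0.19 for dupilumab minus placebo, where proliferation genes were at 0.0674 and eccrine markers at -0.28. There too, eccrine markers under placebo were at 0.43 and adipocyte markers at 0.0796, and fibroblast markers for the dose difference at -0.12. Within set B, interferon genes under placebo were at 1.32, differentiation genes at -0.97 and barrier lipid genes at -0.21; for dupilumab minus placebo barrier lipid genes were at 0.33, mast cell markers at -0.11 and fibroblast markers at -0.0844, and for the dose difference sebaceous gland genes at 2.27. Without one patient, placebo shifts ran from -1.91 to 0.43 for interferon genes, -0.15 to 1.42 for differentiation genes, -0.0303 to 0.76 for barrier lipid genes, -7.21 to 0.43 for eccrine markers and -5.09 to 0.0796 for adipocyte markers. The dose difference of antimicrobial genes ran from -1.68 to 0.0069. For dupilumab minus placebo, fibroblast markers ran from -0.0014 to 0.39 and eccrine markers from -0.0628 to 7.59, and muscle markers in non-lesional skin after dupilumab from -1.26 to 0.0696.

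The signature change at 150 mg ran from -0.84 to -0.46 without one patient. The patient of the biopsy with conflicting labels was among those left out in turn. At 300 mg the change was -1.37 with all arrays unpaired (exact permutation p = 0.0333, which ignores the pairs). At both doses it was -0.87 with signature genes from a fit with the set term (exact p = 0.0547), -0.26 within set A (exact p = 0.625) and -1.55 within set B (exact p = 0.0625, the smallest 5 pairs allow), and ran from -1.28 to -0.65 without one patient.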

Other observations

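The tests of the splits on unadjusted counts were chosen only after the adjusted counts were seen. In lesional against non-lesional skin after dupilumab, 6 lists passed with the preset correlation and 0 with an estimated one. Antimicrobial genes averaged 1.50 (adjusted p = 0.000362, and 0.669 with an estimated correlation; 1 of 17, S100A7, passing adjusted over the list alone) and interferon and Th1 genes 1.38 (0.000362, and 0.669; 3 of 13, OAS1, OAS2 and OASL), where the same means were 3.30 and 1.85 before treatment. Proliferation genes averaged 0.47 (0.0124, and 0.865; 4 of 14, CCNA2, CDK1, RRM2 and NUSAP1), against 1.73 before treatment; this difference between visits was not tested. T cell markers averaged 0.98 (0.0125, and 0.87; 1 of 14, CTLA4), fibroblast markers 0.42 (0.000564, and 0.669; 4 of 10, the collagen genes COL1A1, COL1A2 and COL3A1 and LUM) and adipocyte markers 2.33 (0.00276, and 0.669; 3 of 7, ADIPOQ, PLIN4 and FABP4). Adipocyte markers were higher in lesional skin in 5 of 5 pairs, at 2.15 ± 1.59 (SD; exact sign-flip p = 0.0625, the smallest possible, and 0.688 adjusted over the lists). With the array set as a term the proliferation and adipocyte means were 0.29 and 1.27 (adjusted p = 0.132 and 0.139). Without one 150 mg patient the antimicrobial and adipocyte means were 0.89 and 1.16 (adjusted p = 0.0629 and 0.241), and the adipocyte call was also lost without one 300 mg patient (0.0507). Without another 300 mg patient the T cell mean was 0.64 (0.123), without the former the proliferation mean was 0.22 (0.535), and without another 150 mg patient both calls were lost (0.105 and 0.0921).

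In non-lesional skin after against before dupilumab, 5 lists passed with the preset correlation and 0 with an estimated one. Antimicrobial genes averaged 0.75 (adjusted p = 8.06e-05, and 0.651 with an estimated correlation), proliferation genes 0.37 (9.33e-05, and 0.651), interferon and Th1 genes -0.49 (0.00891, and 0.76), adipocyte markers -1.51 (8.06e-05, and 0.651) and muscle markers -0.53 (0.0265, and 0.76). No member passed adjusted over the list alone, and in the 5 pairs each list moved its way in 3 of 5. Each call was lost in at least 1 refit without one patient, with means then of 0.37 for antimicrobial genes, 0.29 for proliferation genes, -0.15 for interferon genes, -0.44 for adipocyte markers and 0.07 for muscle markers.

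Other splits of the paired samples were counted. After 150 mg, 34 of 64 splits gave as many genes at an unadjusted p under 0.05 as the real 478 (highest other 1299), after 300 mg 10 of 32 gave as many as 1008 (highest other 1310), between doses 85 of 100 as many as 183 (highest other 2344) and in non-lesional skin after dupilumab 28 of 32 as many as 103 (highest other 1415). A random grouping cannot be excluded for these counts, and the splits between doses and in non-lesional skin that gave over 10 times the real count point to a structure of the samples, whose source, the patients or the array sets, was not tested. In lesional against non-lesional skin after dupilumab, 1 of 32 splits, the real one with 97 genes, gave as many, and the highest other, which relabelled 1 pair, gave 48. That share is the smallest that 32 splits allow. Only 1 of the 5 pairs had both biopsies in one array set, so in the others the splits swapped set and tissue together. The splits therefore do not exclude a random grouping, and 0 genes passed with the array set as a term.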
